A study of Mus musculus with 16 samples.

How the data were processed

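RNA-seq libraries from whole mouse retinas, described as poly(A)-selected and strand-marking, were analysed from 2 tables that the authors deposited. The table of 10 uninjected retinas holds FPKM values per gene (fragments scaled by gene length and library size), per the file headers and values, with gene length, symbol and mm10 coordinates beside them. The table of 6 injected retinas holds raw read counts per gene as deposited, with Ensembl gene identifiers. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts 2.0.6 and DESeq2 1.42.0 were used with the mm10 build, and the notes give these names with no role or order. The annotation release and the strand setting of the counting are not given in the sources used here. Symbols for the count table were taken from a reference list of gene names, and coordinates from the FPKM table. Both were matched by gene identifier, without the version suffix. Of 48440 identifiers, 48058 (99.2%) had a symbol. Among FPKM genes, 105 symbols were shared by several identifiers.

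The uninjected groups were wildtype at 12 months (n = 3), Elovl2 mutant at 12 months (n = 3) and wildtype at 18 months (n = 4). The injected groups, at 18 months, were vehicle (n = 3) and the fatty acid 24:5 (24 carbons and 5 double bonds, n = 3). The substitution in Elovl2 is written C234W in the series design and C34W in the genotype labels. The fatty acid was given to 1 eye and vehicle to the fellow eye, and the labels do not say which retinas came from the same animal. The labels do not say that each library is a separate animal, so p-values measure the spread between these samples, which may be partly technical.

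FPKM times gene length is a whole multiple of the worth of 1 read in each library for 99.95% of values above 0, within 0.02 of a whole number, which gave back 12810600 to 30519400 reads per library. The count libraries held 22066700 to 25609200 counts. The structural RNAs Rn7sk, Rpph1 and Rmrp held 8.54% to 13.4% of these counts, so poly(A) selection of the injected libraries is uncertain. The count table listed 37 mitochondrial genes, all at 0 counts, so mitochondrial transcripts were not analysed in the injected retinas. No pair of replicates was identical or alike within counting noise, since chi-square per degree of freedom lay between 3.25 and 47.6 for all pairs within a group.

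FPKM values were tested with limma 3.58.1 in R 4.3.3 (limma-trend, robust) on log2(FPKM + 1), over 13786 of 54532 genes with a mean FPKM of at least 1. All 3 uninjected groups shared 1 fit. Fold changes from this table are on the log2(FPKM + 1) scale, which understates the change of low genes. Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust) with TMM normalisation, over 17466 genes that passed filterByExpr, and levels are given as TMM-normalised CPM, counts scaled to library size. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan foresaw FPKM for the uninjected table, and no change of test was needed.

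The tables were normalised separately, so levels were tested only within a table. Fixed lists of cell types, pathways and contaminating tissues (29 in number) were tested with camera (limma) using a preset correlation of 0.01, and again with an estimated correlation. A list needed at least 5 measured members. The lens list had no measured member in the uninjected table, and the mitochondrially encoded list had none in the injected table, so 28 lists were tested in each comparison. Counts of members are given adjusted over all genes tested and adjusted over the list alone. Age and genotype effects share the 12-month wildtype libraries, so their correlation was set against 100 simulated sets of unchanged groups with the same controls. In these sets each gene was drawn independently of the others. For the age genes after supplementation, 100 genes with the smallest p per direction were used because fewer than 20 passed the threshold.

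Named genes followed a rule fixed before the data were examined. It takes up to 10 genes per direction past the threshold without overlap between groups. Where fewer than 10 pass, it adds the 10 with the smallest p. It also takes up to 4 members of each list with the smallest p, and Elovl2, Elovl4, Elovl5, Fads1, Fads2, Opn1sw, Gfap and C3. Some genes that the rule takes are not reported here. A last part, for genes called in age and genotype and in the opposite direction after supplementation, took none. Cryaa, Malat1, Rpe65, Irf9, Tmem181b-ps and the Y-linked genes, where they are given per library, were chosen after their values were seen.

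The procedure was tested on simulated data with 200 changed genes per comparison. The changed genes were drawn only from genes with many reads, and all genes varied independently of each other. The recovery rates therefore do not hold for low genes and may be too high for the real libraries. At 1.5-fold, 2-fold and 4-fold changes it recovered 41.8%, 73.1% and 89.4% for age (13713 genes), and 29.9%, 70.1% and 87.9% for genotype (13737 genes). For age against genotype (13741 genes) it recovered 31.3%, 79.1% and 97.0%, and for supplementation (17490 genes) 23.9%, 68.7% and 98.5%. False calls were 9 of 145 for age, 4 of 129 for genotype, 8 of 146 for age against genotype and 12 of 139 for supplementation.

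Alternatives planned beforehand were other pseudocounts, low-value filters, scalings, tools and thresholds, library weights, a replicate block, each library left out in turn, and the estimated correlation. Alternatives added after seeing the data were edgeR and DESeq2 (1.42.0) on the recovered reads, a library split by the sign of the first principal component as a term, the lens list mean as a covariate, the removal of 3 structural RNAs, and the list tests with each injected library left out. The split and the lens mean come from the same values that were tested, so p-values and counts with these terms are descriptive only. Genes with near-identical copies, such as Dynlt1b and its neighbour Tmem181b-ps, Ifit1, C4b, the haemoglobin genes and class II genes, may share or lose reads in the counting, and their values are uncertain to that extent.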

Results

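RNA-seq was collected from 16 whole mouse retinas to ask how age, a point mutation of the fatty acid elongase gene Elovl2, and an injected polyunsaturated fatty acid alter retinal transcripts. Uninjected retinas came from wildtype mice at 12 months (n = 3), Elovl2 mutant mice at 12 months (n = 3) and wildtype mice at 18 months (n = 4), with 12810600 to 30519400 reads per library recovered from the FPKM values. Injected retinas came from 18-month mice, collected 5 days after an injection into the vitreous of 0.36 nmol of the fatty acid 24:5 (n = 3) or vehicle in the fellow eye (n = 3), with 22066700 to 25609200 counts per library.

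Elovl2 (ENSMUSG00000021364, chromosome 13, 41182381 to 41220405, mm10), which lengthens long polyunsaturated fatty acids, was at 21.3 ± 1.91 FPKM (SD, n = 3) in wildtype retinas at 12 months. It was at 20.7 ± 1.12 FPKM (SD, n = 3) in mutants and 23.9 ± 0.0705 FPKM (SD, n = 4) in wildtype retinas at 18 months. In injected retinas it was at 67.5 ± 2.72 CPM with vehicle and 66.6 ± 3.93 CPM with 24:5 (SD, n = 3 each). None of these differences passed the threshold, and the mutation is a point mutation, so the RNA level does not check the genotype label. Elovl4, Elovl5, Fads1 and Fads2, which act in the same fatty acid pathway, also had no call. Opn1sw, the short-wavelength cone opsin gene, and the glial gene Gfap had no call in any comparison either.

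The age comparison asked which transcripts differ between wildtype retinas at 18 and 12 months. Gabra2, which encodes a subunit of the GABA-A receptor, had the smallest p. It was at 2.17 ± 0.204 FPKM (SD, n = 4) at 18 months and 5.62 ± 0.669 FPKM (SD, n = 3) at 12 months, without overlap between groups. Its log2 fold change was -1.06 (SE 0.134, limma adjusted p = 0.210), so it did not pass. Gabra2 (ENSMUSG00000000560) lies on chromosome 5 at 70957597 to 71095849. Rell1 (log2 0.61, SE 0.103) and Pgm1 (log2 0.57, SE 0.108), on the same chromosome, were next among the higher genes with Gm28265, and Cmtm6 was lower (log2 -0.34, SE 0.0647). None of these passed either.

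By limma 0 of 13786 genes passed for age, and 503 had an unadjusted p under 0.05, of which 233 were higher and 270 lower at 18 months. On the recovered reads, edgeR called 1 gene, Gabra2 (log2 -1.37, SE 0.153, adjusted p = 0.0274), and DESeq2 called 14. With library quality weights 1246 genes passed, and 1 of the 10 libraries, wildtype 12-month replicate 1, then had a weight of 5.76.

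**Figure D1:**
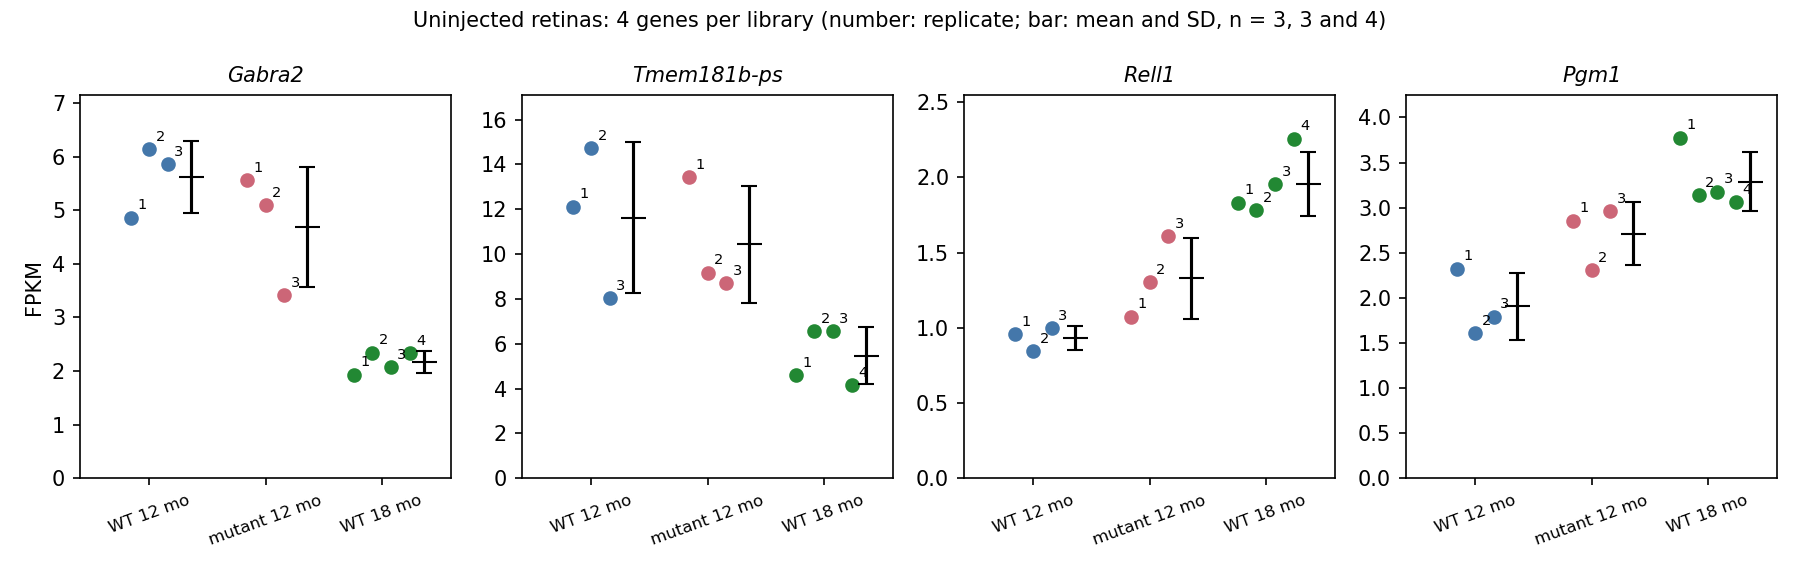
FPKM (y axis, from 0) of Gabra2, Tmem181b-ps, Rell1 and Pgm1 in each uninjected library, grouped as wildtype at 12 months, Elovl2 mutant at 12 months and wildtype at 18 months. Points are libraries numbered by replicate, and bars are the mean and SD (n = 3, 3 and 4); Gabra2 lies between 1.93 and 2.34 FPKM in all 4 libraries at 18 months and at 3.42 or above in all others.

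Among the fixed lists, the mitochondrially encoded genes of the respiratory chain had the largest median shift upward with age. Of 13 members, 12 were higher at 18 months, with a median log2 fold change of 0.40, and 0 passed over all genes or adjusted over the list alone. mt-Co2 was at 396 ± 43.2 FPKM (SD, n = 4) at 18 months and 206 ± 65.6 FPKM (SD, n = 3) at 12 months, and mt-Co1 at 7342 ± 799 and 5596 ± 257 FPKM. Nuclear genes of oxidative phosphorylation were higher in 40 of 45 cases (median log2 0.08), bipolar cell genes in 14 of 17 (median 0.15) and endothelial genes in 9 of 14 (median 0.10), of which 1, Slco1a4, rose when adjusted over the list alone. Visual cycle genes (11 of 13 higher) and circadian genes (13 of 15 higher) had medians of 0.08 each. The pigment epithelium list, which shares 5 genes with the visual cycle list, was higher in 7 of 10 cases (median 0.23, adjusted p = 0.130), with Rpe65 at 15.9 ± 7.31 FPKM (SD, n = 4) at 18 months and 9.26 ± 4.11 FPKM (SD, n = 3) at 12 months. Reactive gliosis genes were lower in 12 of 13 cases (median -0.21), immediate early genes in 7 of 8 (median -0.16) and fibroblast genes in 6 of 6 (median -0.44). In the gliosis list, Gfap was at 13.8, 4.54 and 3.88 FPKM in wildtype 12-month replicates 1, 2 and 3, and at 3.38 to 6.59 FPKM at 18 months. No list was tested with an uninjected library left out. How far a single 12-month library carries these shifts is therefore not known.

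With the preset correlation camera called 6 lists upward and 3 downward for age, with adjusted p from 2.59e-10 for the mitochondrial list to 0.0375 for the circadian list. All 9 calls were lost with an estimated correlation, where the smallest was adjusted p = 0.415. The oxidative phosphorylation call ended with the library split as a term (adjusted p = 0.0928), with which ribbon synapse genes passed upward (0.0166) and unfolded protein (0.0166) and blood genes (0.0220) downward. The libraries also split in a way that crosses the groups. Malat1, a nuclear RNA, was at 229 to 377 FPKM in wildtype 12-month replicates 1 and 2, mutant replicate 1 and wildtype 18-month replicates 2 and 3, and no higher than 149.97 FPKM in the other 5. Rpe65, a pigment epithelium gene, was at 5.72 to 13.6 FPKM in the former and 12.8 to 22.3 FPKM in the latter. The other 19 lists, which include complement, microglia, interferon response and all lipid lists, did not pass, with adjusted p from 0.0617 to 0.966.

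The genotype comparison asked what the Elovl2 mutation changes at 12 months. The gene with the smallest p was the small nucleolar RNA gene Gm25970 (0.578 ± 0.714 FPKM in mutants, 4.38 ± 0.993 FPKM in wildtype, SD, n = 3 each). Ebf1, a transcription factor gene and the only protein-coding one among the 10 genes with the smallest p, was at 3.27 ± 0.11 FPKM in mutants and 2.53 ± 0.115 FPKM in wildtype (SD, n = 3 each). Neither passed. By limma 0 genes passed, 302 had an unadjusted p under 0.05, and edgeR and DESeq2 on the recovered reads called 0 as well. Library quality weights gave 2598 calls, with a weight of 3.86 for mutant replicate 2.

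Mitochondrially encoded genes were higher in mutants in 11 of 13 cases (median log2 0.36), with mt-Co2 at 412 ± 181 FPKM in mutants and 206 ± 65.6 FPKM in wildtype (SD, n = 3 each). Endothelial genes (12 of 14 higher, median 0.12), bipolar genes (15 of 17, median 0.11), amacrine and horizontal genes (12 of 16, median 0.09) and sterol synthesis genes (24 of 29, median 0.06) also lay higher. So did interferon response genes (18 of 23, median 0.12) and ganglion cell genes (10 of 15, median 0.07). The mitochondrial, bipolar and endothelial lists also lay higher with age, against the same 12-month wildtype libraries. Low values in these shared libraries would give both shifts, so they are not independent results. Between 18-month wildtype and mutant retinas these lists did not pass (camera preset adjusted p = 0.364, 0.770 and 0.579). Blood genes, led by Jchain and haemoglobin genes, were lower in 5 of 5 cases (median -0.38), with Hba-a1 at 17.0 ± 9.82 FPKM in mutants and 24.2 ± 7.67 FPKM in wildtype (SD, n = 3 each). No member of these lists passed when adjusted over the list alone. Camera called all 8 with the preset correlation, with adjusted p from 2.1e-07 for the mitochondrial list to 0.0479 for the ganglion list. All 8 calls were lost with an estimated correlation, where the smallest was adjusted p = 0.464. With the library split as a term the sterol, interferon and ganglion calls ended (adjusted p = 0.0826, 0.286 and 0.70), ribbon synapse genes passed upward (0.0158), and unfolded protein (0.0195), heat shock (0.0195) and nuclear oxidative phosphorylation genes (0.0101) passed downward. The other 20 lists had adjusted p from 0.0528 to 0.913.

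Wildtype retinas at 18 months were set against mutants at 12 months to find where the age and genotype effects differ. The mitochondrial transfer RNA gene mt-Tr, at 17.8 ± 5.38 FPKM (SD, n = 4) at 18 months, had 14 to 28 reads per library there and 0 to 1 in mutants (limma adjusted p = 0.728). The neighbouring mt-Tg had 10 to 26 reads at 18 months and was listed at 0 in every mutant library. Slc15a2, a peptide transporter, was at 7.51 ± 1.45 FPKM (SD, n = 4) at 18 months and 3.04 ± 0.189 FPKM (SD, n = 3) in mutants. By limma 0 genes passed, 295 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 9 on the recovered reads. With only these groups in the fit, 2 genes passed.

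Immediate early genes, which respond to neuronal activity and handling, were lower at 18 months than in mutants in 8 of 8 cases (median log2 -0.22, preset adjusted p = 1.09e-06). The call was lost at adjusted p = 0.0648 with an estimated correlation, and 1 member, Dusp1 (7.24 ± 0.583 and 9.59 ± 1.02 FPKM), fell when adjusted over the list alone. Ganglion cell genes were lower in 13 of 15 cases (median -0.10, preset adjusted p = 0.000281), lost at adjusted p = 0.765 with an estimated correlation. The other 26 lists had adjusted p from 0.0541 to 0.804. With the library split as a term 4 lists passed, which were these, nuclear oxidative phosphorylation upward (2.87e-07) and fibroblast genes downward (0.0384).

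Across 13786 genes, which are not independent replicates, the age and genotype log2 fold changes had a Pearson r of 0.55 and a Spearman rank correlation of 0.62. Unchanged groups simulated against the same 12-month wildtype libraries gave a mean r of 0.533 (0.499 to 0.569) and a mean rank correlation of 0.49 (0.471 to 0.509). The covariance was 0.0127, against 0.0173 (0.0154 to 0.0191) in the simulations, a difference of -0.0046. Thus r lay within the simulated range, the rank correlation above it and the covariance below it. Genes were simulated as independent, whereas the first principal component held 43.9% of the variance of the real libraries. The simulated ranges are thus too narrow, and these positions do not decide whether the effects differ from chance. No gene was called in both comparisons, and 74.1% of genes had the same sign. The shared 12-month wildtype libraries raise this share even without any change, and no such share was simulated. Without wildtype 12-month replicate 3 the covariance was 0.0415 and r was 0.80. The shared controls were not split, since with 3 of them a side would hold a single library.

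**Figure D2:**
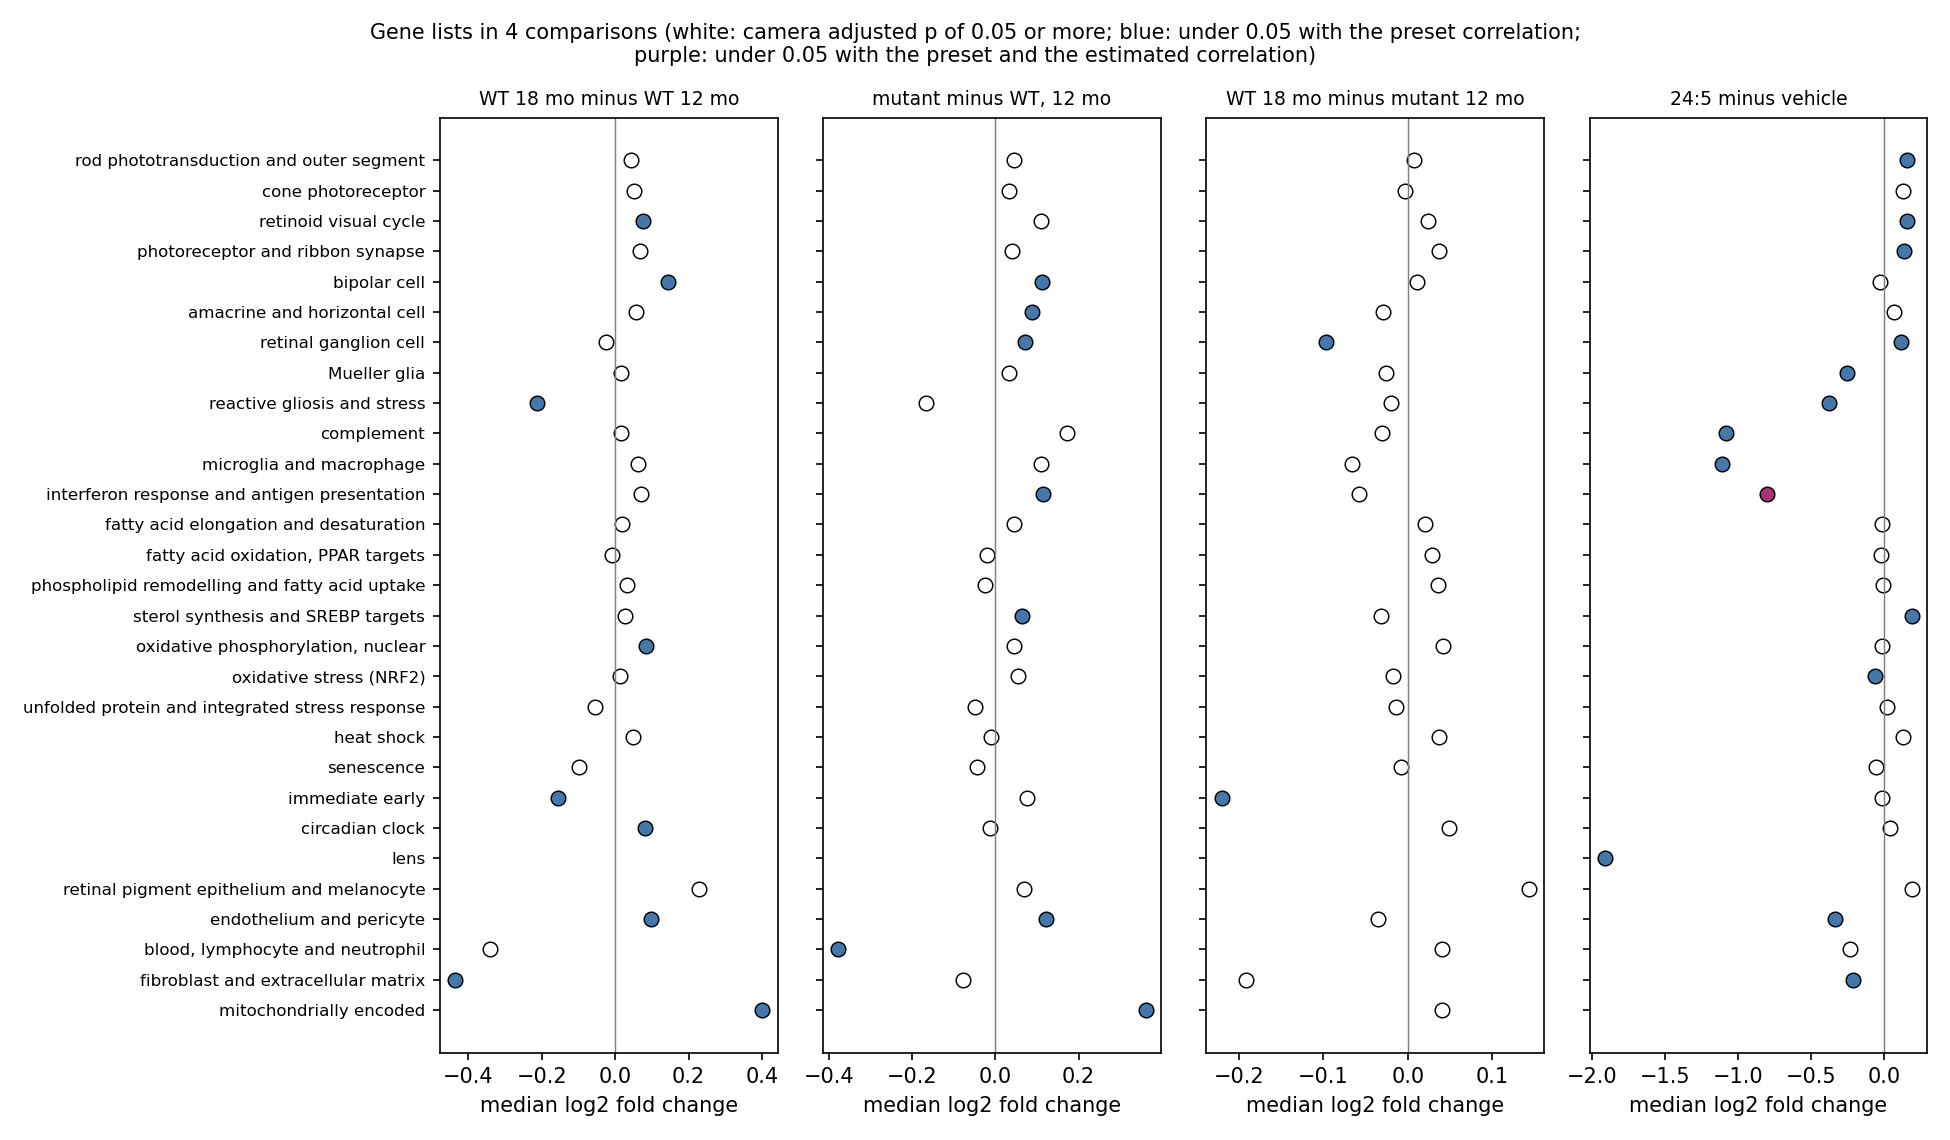
Median log2 fold change (x axis, a separate scale in each panel) of each fixed gene list (y axis) for 4 comparisons: age, genotype, age against genotype, and 24:5 against vehicle. White points did not pass camera with the preset correlation, blue points did, and the purple point also passed with an estimated correlation; the interferon response list after supplementation, at -0.81, is the only purple point.

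The supplementation comparison asked what 24:5 changes in 18-month retinas relative to vehicle. Rnf213 and Ifit1, both induced by interferon, fell. Rnf213 (ENSMUSG00000070327, chromosome 11, 119393100 to 119487418) was at 39.8 ± 3.04 CPM with 24:5 and 90.1 ± 5.31 CPM with vehicle (SD, n = 3 each), 2.26-fold lower (log2 -1.18, SE 0.083, edgeR adjusted p = 0.0117). Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) was at 12.6 ± 0.548 CPM and 25.6 ± 0.53 CPM (SD, n = 3 each), 2.04-fold lower (log2 -1.03, SE 0.088, adjusted p = 0.0257). Next by p, not past the threshold, were the interferon-induced Oasl2 (log2 -1.31, adjusted p = 0.0889) and Parp14 (log2 -0.86), the complement gene C4b (log2 -1.31, adjusted p = 0.144) and the class I light chain gene B2m (log2 -0.75, adjusted p = 0.156). Vwf, H2-T23, Cd93 and P2rx7 followed, all lower with 24:5.

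By edgeR 2 of 17466 genes passed, both lower, and 1154 had an unadjusted p under 0.05, of which 902 were lower and 252 higher with 24:5. DESeq2 called 246 genes (243 lower), 11 passed with quality weights, 85 without a filter, 300 with the library split as a term and 176 with the lens list mean as a covariate, and Rnf213 and Ifit1 were among them each time. The split and the lens mean were taken from these same libraries and take up residual variance. The higher counts with these terms are therefore not evidence of more changes. Without vehicle replicate 1 or 2, or supplemented replicate 2 or 3, 0 genes passed. Without supplemented replicate 1, 1 gene passed, and without vehicle replicate 3, 105.

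Lists of immune genes lay lower with 24:5. Interferon response and antigen presentation genes were lower in 30 of 31 cases (median log2 -0.81), and 17 fell when adjusted over the list alone, 1 of them, Ifit1, over all genes. H2-K1, a class I gene, was at 76.4 ± 13.8 CPM with 24:5 and 134 ± 7.66 CPM with vehicle (SD, n = 3 each). Microglia and macrophage genes were lower in 22 of 22 cases (median -1.11), with 16 lower adjusted over the list alone and 0 over all genes. Its class II genes were at the lower end, with Cd74 at 9.72 ± 3.64 CPM against 56.5 ± 16.3 CPM (SD, n = 3 each, 5.81-fold lower, adjusted p = 0.197) and H2-Ab1 at 6.04 ± 1.51 against 27.7 ± 8.66 CPM. Complement genes were lower in 15 of 17 cases (median -1.08), with 9 lower adjusted over the list alone and 0 over all genes. C3, the central complement component, was at 17.2 ± 3.57 CPM with 24:5 and 105 ± 66.6 CPM with vehicle (SD, n = 3 each, adjusted p = 0.420).

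Camera with the preset correlation gave adjusted p = 1.89e-39 for interferon response, 2.55e-45 for microglia and 1.96e-24 for complement. The interferon call held at adjusted p = 0.0123 with an estimated correlation, while microglia and complement were lost, each at adjusted p = 0.107 with an estimated correlation. The 3 calls with the preset correlation held with each library left out in turn. No overlap between groups, in the lower direction, was found for 18 of 31, 15 of 22 and 9 of 17 members, where 11.6% of all genes did not overlap in either direction and chance gives 10%. An exact permutation test over the 10 splits of the median log2 difference of each list gave p = 0.1, the smallest it can give. For microglia another split came close, at -1.02 against -1.22 for the real split. The largest other split was at -0.62 against -1.07 for complement, and at -0.47 against -0.82 for interferon response. The test also gave 0.1 for the endothelial, fibroblast and ribbon synapse lists. The largest other split was nearly as large for fibroblast (-0.447 against -0.474) and ribbon synapse genes (0.1357 against 0.1365). For endothelial genes it was at -0.236 against -0.353. The test gave 0.2 for the rod, sterol, Müller and ganglion lists. It gave 0.3 for the lens and oxidative stress lists, 0.4 for visual cycle and 0.8 for gliosis.

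**Figure D3:**
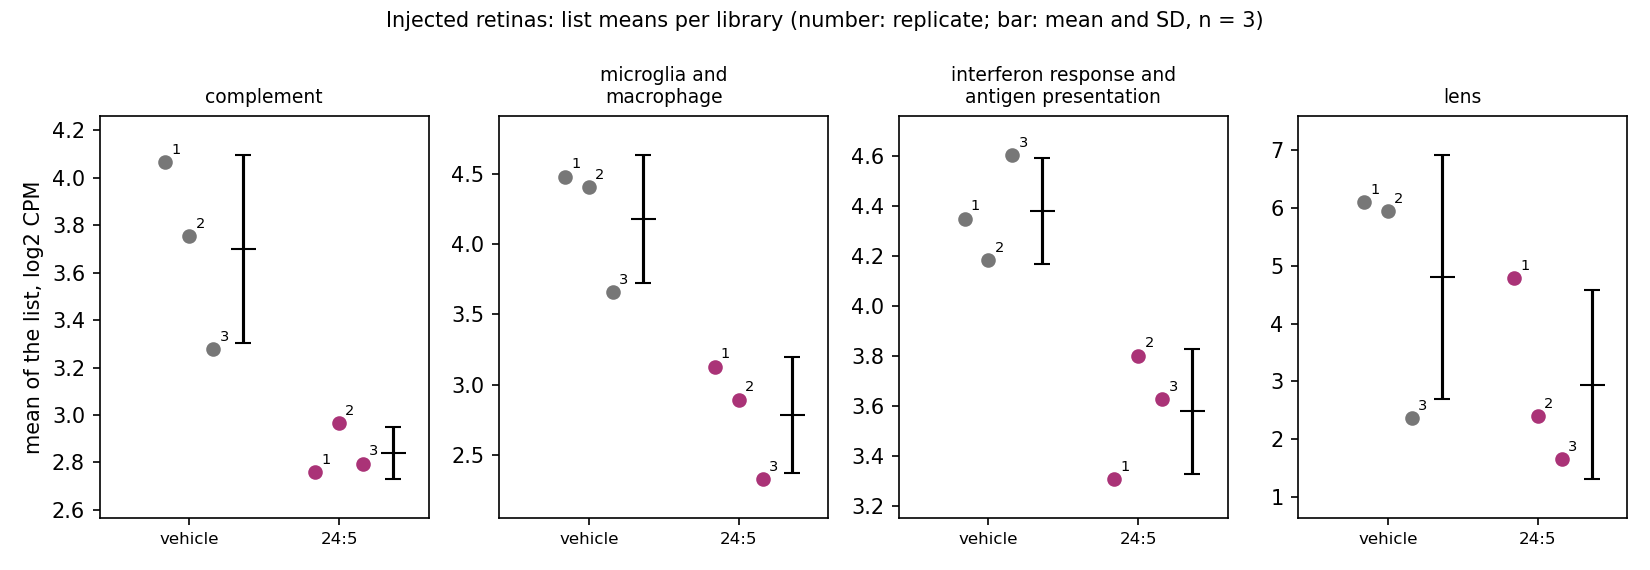
Mean log2 CPM (y axis) of the complement, microglia, interferon response and lens lists in each injected library, for vehicle and 24:5. Points are libraries numbered by replicate, and bars are the mean and SD (n = 3); the 3 immune lists do not overlap between groups, while lens lies at 6.10, 5.94 and 2.36 with vehicle and 4.78, 2.40 and 1.66 with 24:5.

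Lens genes moved the same way in these libraries. All 11 measured members were lower with 24:5 (median log2 -1.91), and 0 passed over all genes or adjusted over the list alone. Cryaa, a lens crystallin, was at 784, 963 and 63.4 CPM in the vehicle libraries and 307, 64.2 and 22.6 CPM in the supplemented ones. The injected libraries also split in a way that crosses the treatment, with the interferon signalling gene Irf9 at 61.0 and 57.7 CPM in vehicle replicates 1 and 2 and 21.6 CPM in supplemented replicate 1, and at 233, 204 and 156 CPM in vehicle replicate 3 and supplemented replicates 2 and 3 (without TMM). Camera gave adjusted p = 0.000133 for the lens list, lost at adjusted p = 0.504 with an estimated correlation. Endothelial genes were lower in 16 of 18 cases (median -0.34, adjusted p = 4.17e-07), with Vwf at 27.1 ± 3.55 and 55.0 ± 7.98 CPM (SD, n = 3 each) as the 1 member adjusted over the list alone, and were lost at adjusted p = 0.143 with an estimated correlation.

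Müller glia genes were lower in 10 of 16 cases (median -0.25, adjusted p = 0.00165, lost at adjusted p = 0.143 with an estimated correlation). Its members Clu (895 ± 80.5 and 1305 ± 209 CPM), Apoe (457 ± 90.4 and 791 ± 128 CPM) and Prdx6 fell when adjusted over the list alone. Fibroblast genes (11 of 15 lower, median -0.21, adjusted p = 0.00485) were lost at adjusted p = 0.481 with an estimated correlation, and without vehicle replicate 1 (0.146) or supplemented replicate 3 (0.103). Oxidative stress genes (16 of 24 lower, median -0.06, adjusted p = 0.0306) were lost at adjusted p = 0.234 with an estimated correlation, and without vehicle replicate 3, supplemented replicate 1 or supplemented replicate 2 (0.243, 0.169 and 0.0594). The estimated correlation was -0.0070 for this list and -0.0015 for the Müller list, both under the preset 0.01. Correlation between genes thus does not account for the loss of either call in that test. For the other lists too, a call lost in that test does not by itself show that correlation between genes removed it. Reactive gliosis genes were lower in 13 of 19 cases (median -0.38, adjusted p = 0.0262) and were lost at adjusted p = 0.743 with an estimated correlation. Without supplemented replicate 1 the gliosis median was 0.00 and adjusted p = 0.209, and without vehicle replicate 3 adjusted p = 0.654.

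Other lists lay higher with 24:5. Sterol synthesis genes were higher in 27 of 30 cases (median log2 0.19, adjusted p = 4.27e-07), lost at adjusted p = 0.255 with an estimated correlation. Insig1, a sterol sensor partner, was at 101 ± 7.7 CPM with 24:5 and 77.3 ± 8.16 CPM with vehicle (SD, n = 3 each). Rod genes were higher in 26 of 27 cases (median 0.15, adjusted p = 1.43e-06), lost at adjusted p = 0.481 with an estimated correlation. Rom1, of the outer segment disc rim, was at 2183 ± 112 CPM with 24:5 and 1877 ± 38.2 CPM with vehicle (SD, n = 3 each). Ganglion cell genes (13 of 15 higher, median 0.11, adjusted p = 0.00165) were lost at adjusted p = 0.234 with an estimated correlation. No member of the sterol, rod or ganglion lists passed, over all genes or adjusted over the list alone. Of sterol and rod genes 30% and 14.8% did not overlap between groups, against 11.6% of all genes.

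Visual cycle genes (11 of 13 higher, median 0.15, adjusted p = 0.0083) and ribbon synapse genes (15 of 17, median 0.14, adjusted p = 0.0384) were lost, each at adjusted p = 0.481 with an estimated correlation. Without vehicle replicate 3 or supplemented replicate 1 the visual cycle call ended (0.182 and 0.0739). The synapse call ended without vehicle replicate 1 or 3 (0.146 and 0.055) or supplemented replicate 2 or 3 (0.0743 and 0.132), with the library split as a term (0.089) and with the lens list mean as a covariate (0.336). With 1 library left out some medians moved by more than 1.5 times. Without vehicle replicate 1 the medians were 0.10 for visual cycle, 0.08 for ribbon synapse, -0.13 for fibroblast and -0.12 for oxidative stress genes. Without vehicle replicate 2 they were 0.28 for visual cycle, -0.62 for gliosis, -0.50 for fibroblast and -0.11 for oxidative stress genes. Without vehicle replicate 3 they were 0.05 for visual cycle, 0.08 for rod, -0.06 for gliosis, -0.51 for fibroblast and -0.04 for oxidative stress genes. Without supplemented replicate 1 they were -3.61 for lens, -0.65 for fibroblast and -0.03 for oxidative stress genes. Without supplemented replicate 2 they were 0.06 for ribbon synapse, 0.18 for ganglion and -0.76 for gliosis genes, and without supplemented replicate 3 they were 0.04 for ribbon synapse, 0.12 for sterol, -0.22 for endothelial and -0.10 for oxidative stress genes. Of the visual cycle and synapse lists only Dag1, in the synapse list, passed adjusted over the list alone, and it fell (48.2 ± 0.906 and 58.5 ± 1.25 CPM, SD, n = 3 each). The other 14 lists, which include fatty acid elongation, fatty acid oxidation and phospholipid remodelling, had adjusted p from 0.0559 to 0.860. Some of these passed with 1 library left out. Without vehicle replicate 2, cone (adjusted p = 0.00144), amacrine and horizontal (0.0121), pigment epithelium (1.3e-09), senescence (0.0298) and blood genes (0.0396) passed. Without vehicle replicate 1, oxidative phosphorylation (0.0192) and pigment epithelium genes (0.0452) passed, and without vehicle replicate 3, amacrine and horizontal (0.0197) and heat shock genes (0.0198). Without supplemented replicate 1, bipolar (0.0487), heat shock (0.00945) and immediate early genes (0.00355) passed, without supplemented replicate 2 senescence genes (0.0250), and without supplemented replicate 3 cone (0.0117), senescence (0.00709) and pigment epithelium genes (0.0199). With the library split as a term, cone (0.000236) and pigment epithelium genes (0.000575) passed upward, and senescence (0.0092) and immediate early genes (1.96e-05) downward. With the lens list mean as a covariate the same lists passed (7.04e-05, 2.55e-06, 0.00753 and 3.05e-05), as did oxidative phosphorylation genes upward (0.00774). Elovl5 was at 39.8 ± 2.01 CPM with 24:5 and 46.3 ± 0.569 CPM with vehicle, and Fads2 at 29.6 ± 5.26 and 38.1 ± 4.53 CPM (SD, n = 3 each), neither past the threshold.

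**Figure D4:**
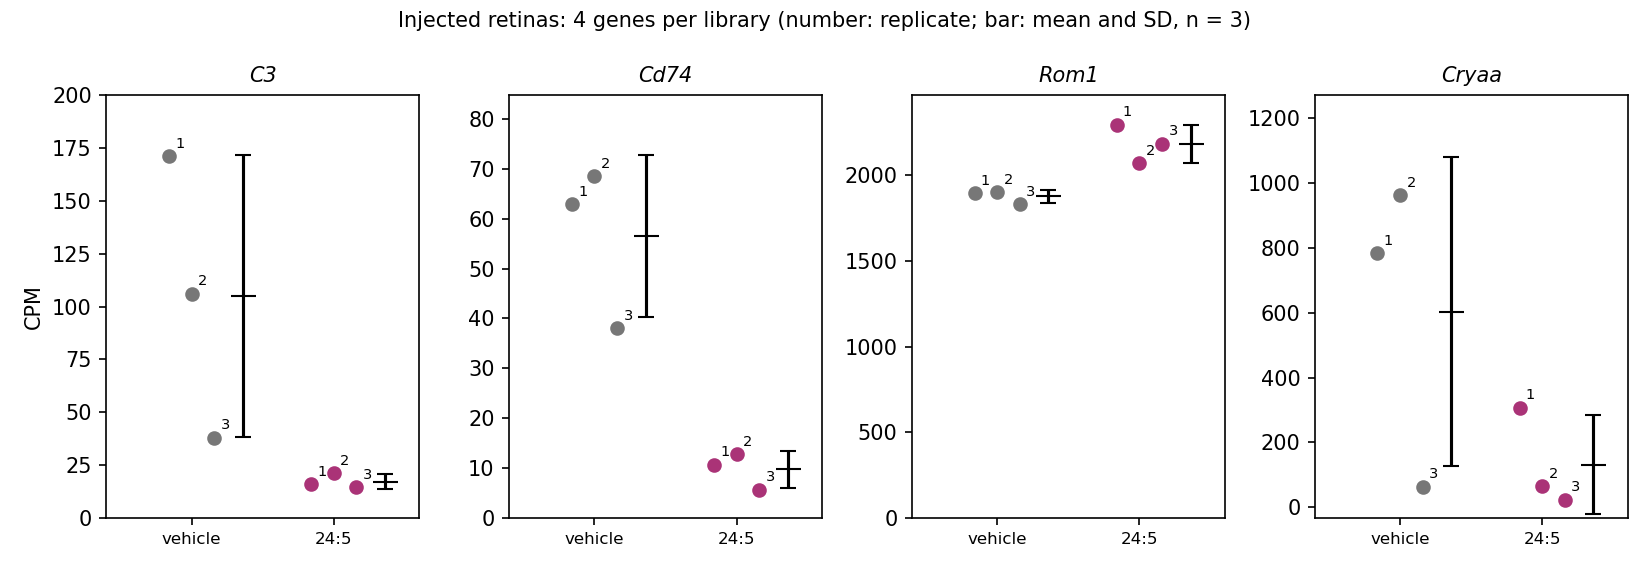
CPM (y axis) of C3, Cd74, Rom1 and Cryaa in each injected library, for vehicle and 24:5. Points are libraries numbered by replicate, and bars are the mean and SD (n = 3); C3, Cd74 and Rom1 do not overlap between groups, and Cryaa spans 63.4 to 963 CPM within the vehicle group.

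The 100 genes with the smallest p in each direction for age and for genotype were then followed in the injected retinas, to ask whether 24:5 moves them the opposite way. These sets come from genes that did not pass the threshold. The genes higher at 18 months had a median log2 fold change of 0.01 after 24:5 (44 of 79 measured genes higher) and those lower at 18 months 0.01 (50 of 87 higher). Genes higher in mutants had a median of 0.06 (52 of 84 higher) and those lower in mutants 0.04 (53 of 82 higher), while all genes had a median of 0.00. Camera gave adjusted p = 0.170, 0.0731, 0.0731 and 0.0731, and 0.153 for each with an estimated correlation. The exact permutation p over 10 splits was 0.4, 0.7, 0.2 and 0.5. Without supplemented replicate 1 the set higher in mutants passed upward (median 0.05, adjusted p = 0.0452). The tables also differ in the sex of the animals, since the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 in all 10 uninjected libraries and at 47.1 to 149 CPM, without TMM, in all 6 injected ones.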

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

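Of 28 values tested for a library far from the others, 1 stood apart, and this test was chosen before the data were examined. Pgm1, a sugar phosphate metabolism gene, was at 3.78 FPKM in wildtype 18-month replicate 1, while the other 3 libraries of that group were at 3.06 to 3.18 FPKM. The gap to the nearest of these was 0.837 of the range of the group, just above the 95% critical value of Dixon's test for 4 samples. By chance about 1 in 20 groups would stand out in this way.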

How the results depend on the processing

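The tests on recovered reads, the library split as a term, the lens list mean as a covariate, the removal of structural RNAs and the list tests without single injected libraries were chosen after seeing the data. For age, limma called 0 genes, and 4 passed without a filter, 1 with a mean FPKM of at least 0.1, 1246 (710 higher, 536 lower) with array quality weights, 1 with the library split, 1 by edgeR and 14 by DESeq2 on recovered reads. For genotype, 4 passed without a filter, 1 with a mean FPKM of at least 0.1 and 2598 with array quality weights, against 0. For age against genotype, 1 passed without a filter, 2 with only the groups compared, 5 with array quality weights, 1 with the library split and 9 by DESeq2 on recovered reads, against 0. For supplementation, 2 genes became 246 by DESeq2 (3 higher, 243 lower), 85 without a filter, 11 by voom with quality weights, 300 with the library split and 176 with the lens covariate. With 1 library left out the count lay between 0 and 105, the latter without vehicle replicate 3. It was 2 with RLE size factors, with a mean count of at least 10 and without 3 structural RNAs, and 3 at an adjusted p under 0.1. The cause of these moves was not tested, except that a fit with fewer libraries has less information.

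With an estimated correlation, the lists past the threshold went from 9 to 0 for age, 8 to 0 for genotype, 2 to 0 for age against genotype and 14 to 1 for supplementation. The Müller and oxidative stress calls after supplementation were lost although their estimated correlations lay under the preset. These losses are therefore not all due to correlation between genes. With the library split, 4 lists passed for age against genotype. Nuclear oxidative phosphorylation genes turned to a median of -0.0594 for genotype with the library split and passed downward (adjusted p = 0.0101). After supplementation, reactive gliosis genes ranged from -0.76 to 0.00425 with 1 library left out and turned without supplemented replicate 1. Immediate early genes, with a negative median but ranked upward by camera, were ranked downward with the library split (median -0.24) and the lens covariate (-0.45). A list whose direction changed with neither test past the threshold was counted as the same. Of the list results 439 were the same, 53 weaker, 35 stronger and 4 reversed. Of the named genes 8293 results were the same, 244 stronger and 9 weaker, and all 45 marker means moved by less than 1 SD with another scaling. A named gene past the threshold in neither fit also counted as the same, whatever its direction. Only Rnf213 and Ifit1 passed in a main fit, so the count of the same says little about stability.

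The Pearson r of age and genotype effects ranged from 0.594 to 0.798 with 1 control left out, and the covariance from 0.0151 to 0.0415, or 0.0280 with a pseudocount of 0.1. Values with 1 control left out have no simulated range of their own, and fewer shared controls raise them even without any change. The set of genes higher in mutants had medians after supplementation from 0.0221 to 0.0607 with 1 library left out. It exceeded randomly drawn genes of like expression (random matched sets) by 0.0507, at percentile 99.9, and the set lower in mutants did by 0.0342, at percentile 97.7. These percentiles treat genes as independent and do not measure the spread between samples. Over the splits of the samples the exact permutation p was 0.2 and 0.5 for these sets. With 1 library left out the set lower in mutants had medians from 0.00343 to 0.0573. The sets higher and lower at 18 months then had medians from 0.00466 to 0.0493 and from 0.0102 to 0.0495. The cause was not tested.

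The labels do not say whether equal replicate numbers mark the same animal, and the data do not settle it. Deviations of same-numbered vehicle and supplemented libraries correlated at 0.40, -0.20 and 0.42, and 4 of 6 libraries correlated best with their own number. With the replicate block 88 genes passed for supplementation and 0 in each uninjected comparison. Under the block the visual cycle call for age (adjusted p = 0.0616) and the ganglion call for genotype (0.0584) ended, interferon response passed for age (0.0152), and cone, amacrine and heat shock genes passed for supplementation (0.0426 each).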

Other observations

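All tests of explanations below, and the splits of the samples, were chosen or worded after the result was seen. Genes that handle lipids outside the elongation pathway went both ways with 24:5, none past the threshold. The lipid droplet gene Plin2 was at 10.6 ± 1.04 CPM with 24:5 and 15.8 ± 3.14 CPM with vehicle, and the fatty acid carrier gene Fabp5 at 23.8 ± 2.02 and 35.8 ± 8.28 CPM (SD, n = 3 each). Acadvl, of mitochondrial fatty acid oxidation, was at 92.3 ± 5.85 and 76.9 ± 2.89 CPM. In the senescence list 1 gene fell adjusted over the list alone, Igfbp5, at 50.8 ± 3.04 and 73.9 ± 8.12 CPM (SD, n = 3 each). The lists of fatty acid oxidation, nuclear oxidative phosphorylation and immediate early genes had negative medians and means while camera ranked them upward, and the pigment epithelium list had a median of 0.19 and a mean of -0.003, none past the threshold.

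In the uninjected retinas the stress response gene Trib3 was at 4.24 ± 0.349 FPKM (SD, n = 4) at 18 months and 6.37 ± 1.1 FPKM (SD, n = 3) in mutants, and mt-Nd3 was at 197 ± 23.9 and 86.2 ± 28.5 FPKM. Neither passed over all genes. Adjusted over the list alone, Trib3 was the 1 member of the unfolded protein list that was lower at 18 months, and mt-Nd3 the 1 member of the mitochondrially encoded list that was higher, while neither list passed camera.

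Other splits of the samples bear on the counts of genes. For age (highest other 3) and age against genotype (highest other 1) the real split called 0 genes, which all 35 of 35 splits reach by construction, so these splits decide nothing about chance. For genotype (real 0, highest other 2018, as many in 10 of 10 by construction) and supplementation (real 2, highest other 1315, as many in 2 of 10) the splits are too few for a share under 0.05. The split with 1315 genes set vehicle replicates 1 and 2 and supplemented replicate 1 against the rest, which points to a structure of the samples that crosses the treatment.

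The complement, microglia and interferon lists lay lower with 24:5, with a median log2 fold change of -0.95 over 70 genes. Lens tissue carried over with the vehicle retinas, and the library split, are each argued against as the whole cause, since the median was -0.82 with the lens list mean as a covariate and -0.87 with the split as a term. Within the sides of the split it was -0.99 and -0.80, each from an arm of 1 library against 2, as values with no test. Relative to 5 homeostatic genes, 9 of 17 other microglia genes were lower in every supplemented library (52.9%, where chance gives 5% for a single gene). These genes share that reference and move together (estimated correlation of the list 0.543). The share therefore cannot decide whether fewer resident microglia were the whole cause. The homeostatic genes were themselves lower in 5 of 5 cases (median -0.70, median SE 0.35). Comparing their median with that of the list (-1.11), which was the first test considered, would not have excluded fewer microglia either. Fewer microglia thus stay open as part or the whole of the pattern. A response to 24:5 and a difference between eyes in the reaction to the injection stay open, and no untreated eye of the same animals was analysed here.

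Gabra2 was lower at 18 months, with a log2 fold change of -1.06 that was -1.05 with the library split as a term, which argues against the split as its cause. A strain variant carried by the 18-month animals is a candidate explanation, because an intronic deletion that lowers Gabra2 RNA is known in C57BL/6J mice. Of the 50 genes with the smallest p for age, 11 had a partner within 1 Mb, against a mean of 3.87 in random draws, 98.8% of which had fewer, while 8 and 7 had one for genotype and age against genotype, above 88.9% and 86.5% of the draws. This is weak evidence, since the pairs include near-identical copies and gene clusters such as Gm28265 and Gm10830, although Rell1 and Pgm1 lie together on chromosome 5. Gabra2 was at 15.6 to 18.8 CPM of recovered reads in wildtype at 18 months, 40.8 to 49.0 CPM in wildtype and 27.5 to 44.8 CPM in mutants at 12 months, and 16.1 to 22.8 CPM, without TMM, in the injected table, which was not tested against the other, and age itself stays open.

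The uninjected libraries split on the first principal component (43.9% of the variance) in a way that crosses the groups. A difference in the share of nuclear RNA may contribute, since the median loading of 303 long intergenic noncoding RNAs was at percentile 0 of random genes of like expression. Pigment epithelium carried over may contribute as well, since its 10 genes were at percentile 100, on the opposite side. The tests do not separate these, and no biological explanation was tested.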
